A study of Escherichia coli str. K-12 substr. MG1655 with 20 samples.

How the data were processed

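RNA sequencing libraries from 20 cultures of Escherichia coli K-12 MG1655 derivatives were analysed as 1 table of gene values. Ribosomal RNA was depleted before sequencing, per the labels' protocols, and reads were processed with Bowtie, per the submitters' processing notes, with version, genome build and counting tool not given in the sources used here. The authors deposited values named RPKM. Checked against gene lengths, they were per base pair and not per kilobase, scaled to library size, so each value was multiplied by 1000 to give RPKM. In each library 96.1 to 96.9% of low values were whole multiples of 1 step within a tolerance of 0.1, which gave the reads per library (1868600 to 6664800) and the reads behind each gene. One read in a gene of 1 kb was 0.15 to 0.535 RPKM. A value of 0 allows up to 1.61 RPKM for such a gene in the shallowest library, taking 3 reads as the limit. Counting intervals are exact binomial 95% intervals and, like this limit, cover counting error only. Those of the trans-zeatin excess are Fisher's exact intervals scaled by depth. The intervals for the genes of single pairs and for the named trans-zeatin genes were added after seeing the data.

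The table had 4291 entries. The PhoQ construct entry was infinite in every library and was left out, as were 5 other construct entries in the gene tests. Gene names were matched to the ASM584v2 annotation for names and lengths alone; 4213 entries matched. No coordinates are given because the build is not named.

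Groups followed the sample titles. The treatment protocol gives the magnesium conditions of the same samples the other way round, and the characteristics give millimolar where titles and protocol give micromolar amounts; the micromolar values were used. Values were analysed as log2(RPKM + 1). Genes with a mean of at least 5 RPKM over 20 libraries, 3147 in all, were tested with limma 3.58.1 in R 4.3.3, with the variance trend on and Benjamini-Hochberg adjustment at 0.05. The comparisons were wild-type magnesium response (2 against 2 libraries, 2 residual degrees of freedom), magnesium response of the 6 pairs with pair as a block, the difference between those responses, and pairs against wild type in each condition. The 6 pairs are different strains with 1 library each per condition, so p-values measure spread between these strains and cultures. The numbers of the wild-type replicates did not pair them: deviations of same-numbered libraries correlated at -0.0496 across genes. The replicates were not duplicates of 1 library, with a chi-square per degree of freedom of 11.3 at 10 µM and 4.34 at 50 mM against counting error.

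Of 46 gene lists fixed before the data were examined, the 34 with at least 3 measured genes were tested with camera at an inter-gene correlation of 0.01, adjusted within each comparison. The per-strain median response of the PhoP list was compared by exact permutation. Single pairs and trans-zeatin responses, which have no replicates, were counted by size, at least 4-fold from both wild-type libraries and at least 2-fold respectively, with at least 20 RPKM in the higher library. Lists in the trans-zeatin libraries were ranked among 10000 random lists matched on mean expression over the 20 libraries.

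Genes were named by a rule set before the data were examined: up to 8 highest and 8 lowest called genes for each magnesium response with all libraries moving one way, up to 6 each for pairs against wild type, up to 3 per pair alone, 10 each way for trans-zeatin, and members of called lists. For trans-zeatin, the rule kept only genes whose log2 change in AQ4-PhoP4 was at least 2 times that in PhoQwt-PhoP4 in size. Genes named outside this rule were chosen after their values were seen.

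The tests were tried on simulated reads with 200 changed genes among 3106. The changed genes were drawn only from those with a mean of at least 20 RPKM in the libraries compared. The recovery rates therefore do not cover the tested genes between 5 and 20 RPKM. For the wild-type response 42.7, 80.0 and 99.1% of genes changed 1.5-, 2- and 4-fold were recovered; for the pairs' response 80.9, 97.9 and 99.7%; for the difference in response 18.8, 60.9 and 96.7%; for pairs against wild type at 10 µM 34.9, 80.3 and 98.5%, and at 50 mM 66.3, 91.0 and 98.8%. With no change simulated, 0 genes and 0 lists were called. Noise was drawn for each gene separately, without correlation between genes or an outlying strain. Recovery may therefore be lower and false calls more frequent in the real data, and the 0 lists say nothing about correlated genes. Alternatives covered pseudocounts of 0.25 and 4, filters, rescaling, the variance trend, blocks and leaving out each library. Limma voom on recovered reads, leaving pair 4 out of the single-pair count and testing the called lists without each library or pair were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.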

Results

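The transcriptome of Escherichia coli was measured by RNA sequencing in 20 libraries from strains lacking the chromosomal phoPQ and lacZYA genes and carrying a PhoQ/PhoP pair. PhoQ is a sensor kinase that responds to low magnesium, and PhoP is its response regulator. In 6 strains, named pair 1, 4, 8, 13, 14 and 15, the interface between kinase and regulator had been re-engineered. The labels name the regulator of pair 4 PhoP4. A magnesium series of 16 libraries compared cells at 10 µM and 50 mM MgSO4 after 30 min, with 2 wild-type libraries and 1 library of each of the 6 pairs per condition. A further 4 libraries, 1 per strain and condition, held cells at 2 mM MgSO4 with 0 or 1 µM of the plant hormone trans-zeatin. One of those strains carried PhoP4 with a chimeric trans-zeatin sensor (AQ4-PhoP4), and the other carried PhoP4 with wild-type PhoQ (PhoQwt-PhoP4), which the labels call an incompatible pair. The depth recovered from the values ran from 1868600 to 6664800 reads per library.

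The first comparison checked the labels and the stimulus. The lacZ, lacY and lacA genes lay at or near 0 RPKM in the libraries, with the highest value at 0.715 RPKM for lacA in pair 4 at 10 µM. The phoP gene ranged from 349 RPKM in AQ4-PhoP4 with trans-zeatin to 861 RPKM in pair 14 at 50 mM. The phoQ gene lay between 326 and 439 RPKM in the magnesium series. It lay at 38.5 and 37.7 RPKM in PhoQwt-PhoP4 and at 55.6 and 51.5 RPKM in AQ4-PhoP4. The treatment protocol assigns the magnesium conditions the other way round from the sample titles, and groups here follow the titles. The magnesium transporter gene mgtA read 186 and 75.3 RPKM in the wild-type libraries titled 10 µM and 3.22 and 2.30 RPKM in those titled 50 mM. By the protocol, low-magnesium cells were also pelleted, washed and resuspended while high-magnesium cells were only diluted, so magnesium and handling changed together in every magnesium contrast.

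With the natural pair, low magnesium changed 454 of 3147 genes in limma at an adjusted p under 0.05, of which 301 were higher and 153 lower at 10 µM. Of these, 98 changed at least 2-fold, 65 upward and 33 downward. The count was 0 without the filter on low values and 17 without limma's variance trend. It also rested on single libraries, since it was 903 without 10 µM replicate 1, 29 without 50 mM replicate 1 and 41 without 50 mM replicate 2. The median gene rose by 0.13 on the log2 scale. When each library was rescaled by its median ratio, the shift was 0.01 and the split became 128 higher and 186 lower. PhoP-activated genes were among the largest increases. The largest change was in ybjX, at 606 ± 110 RPKM at 10 µM against 7.18 ± 1.59 RPKM at 50 mM (SD, n = 2), a log2 change of 6.22 ± 0.20 (SE, limma adjusted p 0.000476). The log2 change was 5.18 for yneM (mgtS), 5.15 for mgrB, 5.00 for mgtA, 4.95 for the leader mgtL, 4.26 for the pyruvate-transporter gene yjiY, 4.09 for rstA and 3.85 for rstB. Among genes that fell, the gluconate genes gntT and gntU changed by -4.68 and -3.08, and gntK fell from 92.3 ± 13.1 to 10.7 ± 2.0 RPKM (SD, n = 2). They were followed by ygdQ at -1.59, ygiW at -1.58, livJ at -1.48, the porin gene ompC at -1.43 and sufA at -1.41.

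The same contrast across the re-engineered pairs, with pair as a block, asked whether the 6 pairs still answered magnesium. It gave 517 genes in limma, 290 higher and 227 lower, of which 70 changed at least 2-fold, 50 upward and 20 downward. Without pair 15 the count was 284, and without pair 13 it was 330. The largest increases were in mgtA, from 3.30 ± 0.52 to 424 ± 411 RPKM (SD, n = 6), with a log2 change of 6.22 ± 0.36 (SE, limma adjusted p 2.37e-06). The log2 change was 5.62 for mgtL, 5.53 for yneM, 5.26 for mgrB, 4.10 for ybjX, 3.75 for the nitrogen-regulatory gene glnK, 3.23 for yjiY and 3.03 for the zinc-stress gene zraP. The largest decreases were -4.70 in gntT, -3.72 in gntK and -3.47 in gntU, then -1.91 in yoaE, -1.45 in yedE, -1.37 in metE, -1.32 in nrdH and -1.31 in yedF. A total of 216 genes were called in both wild type and pairs, and 216 of them moved in the same direction. Across genes, the response of single pairs correlated with the mean wild-type response at a Pearson r from 0.47 in pair 1 to 0.71 in pair 14, beside 0.62 between the wild-type replicates. The 2 kinds of r are not alike, because the mean of 2 wild-type responses carries less noise than a single one. An r above 0.62 therefore does not mean that a pair followed wild type more closely than the wild-type replicates followed each other. Genes are not independent replicates, so these values carry no p.

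**Figure D1:**
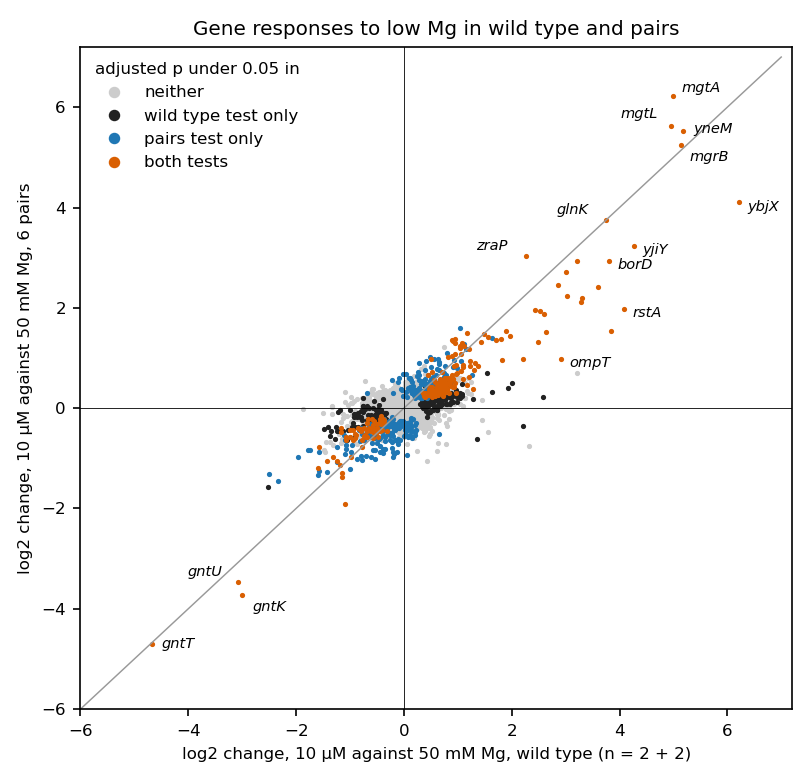
Log2 change at 10 µM against 50 mM MgSO4 in wild type (x axis, 2 libraries per condition) and in the 6 pairs (y axis), 1 point per gene, coloured by the limma test that called it; the line marks equal change. The 216 genes called in both lie in the quadrants of equal direction, with mgtA at 5.00 and 6.22 and gntT at -4.68 and -4.70.

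Among 34 gene lists fixed beforehand, camera, which compares a list with all other genes, called 10 in wild type and 13 in the pairs at a preset inter-gene correlation of 0.01. None of the 49 calls over 5 comparisons held when the correlation was estimated. In wild type 13 of 14 PhoP-activated genes rose, and 13 rose when adjusted over the list alone. The same counts, 13 and 13, held in the pairs. Nitrogen-limitation genes of the NtrB/NtrC system rose in both, 13 of 19 in wild type and 16 of 19 in the pairs, with glnK at 3.75 in each. Histidine and tryptophan genes rose in both, with 8 of 13 called in each and hisC at 1.17 and 1.49. Sulfate-assimilation genes fell, 3 of 15 in wild type and 12 of 15 in the pairs, with cysP at -1.15 and -1.30. The wild-type call was lost without 10 µM replicate 1, where the list median was -0.13 instead of -0.45. It was -0.85 without 10 µM replicate 2. Pair 14 went against the other pairs, with a median deviation of 0.52 at 10 µM and 0.14 at 50 mM. Ribosomal protein genes fell in 16 of 29 members in wild type and in 5 of 29 in the pairs, and arginine genes fell in 2 and 3 of 11. The arginine call in wild type was lost without 10 µM replicate 1 (median -0.20) and without 50 mM replicate 1 (-0.10). The Fur-repressed iron genes had a median of -0.88 in wild type, with 0 of 20 called, and -0.64 in the pairs, with 11 called. The wild-type median was -0.23 without 50 mM replicate 2 and -1.62 without 50 mM replicate 1. Called in wild type but not in the pairs were the CpxR list, with cpxP at 1.37, the heat-shock list, with ibpA at -1.06, and the ArcA-repressed list, with gltA at -1.18. Called in the pairs but not in wild type were the NarL/NarP, PhoB and RpoS lists, which rose, and the methionine, purine and sigma-E lists, which fell. The ArcA-repressed call was lost without 10 µM replicate 2 (median -0.06) or 50 mM replicate 1 (-0.09). Among the calls in the pairs, PhoB was lost without pair 8 (0.29) or 14 (0.15), RpoS without pair 14 (0.25), 1 (0.26) or 4 (0.24), sigma-E without pair 8 (-0.11) or 13 (-0.08), and purine without pair 14 (-0.09). A camera test of the difference itself called the CpxR, heat-shock, ArcA-repressed, RpoS, methionine and purine lists, but not the NarL/NarP, PhoB or sigma-E lists. The methionine call there was lost without wild-type 10 µM replicate 2 (median -0.27).

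The difference itself was tested by the interaction of condition and class. It called 0 of 3147 genes in limma, beside 440 at an unadjusted p under 0.05, and voom on the recovered reads also called 0. Pair 14 decided this count, since 149 genes were called without it, 52 with a positive and 97 with a negative difference (pairs minus wild type), which are signs of the difference and not sizes of the response. Without pair 15, 2 genes were called. Adjusted over the list alone, 6 of the 14 PhoP targets responded less in the pairs than in wild type. The median response of the PhoP list per strain was 3.92 and 2.93 in the wild-type replicates and 2.24, 2.36, 2.97, 1.96, 1.81 and 1.93 in pairs 8, 14, 15, 13, 1 and 4. The pairs rose in 6 of 6 strains, at 2.21 ± 0.42 (SD, n = 6), with a two-sided exact sign-flip p of 0.0312, the smallest these strains allow. Their mean lay 1.22 below the wild-type mean of 3.43, with an exact two-sided permutation p of 0.0714 over 28 splits, where the smallest possible is 0.0357. The difference was not past the threshold, and it depended on matching wild-type replicates by number, as the p was 0.0357 with the replicates crossed. It also depended on the summary of the list, as list means in place of medians gave a difference of -0.60 (exact permutation p 0.143).

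**Figure D2:**
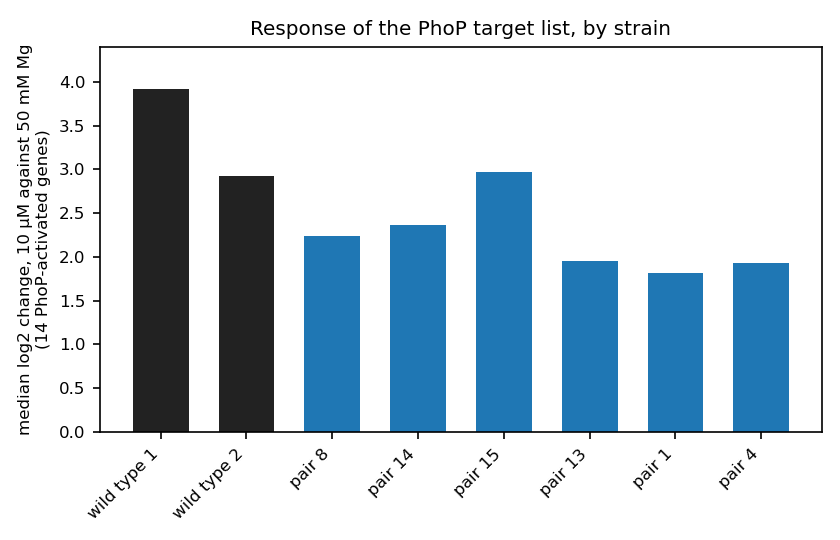
Median log2 change of 14 PhoP-activated genes at 10 µM against 50 mM MgSO4 (y axis) in each strain (x axis), 1 bar per strain or wild-type replicate, with no replicates per pair. Wild type stood at 3.92 and 2.93 and the pairs between 1.81 and 2.97.

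Comparing levels within a condition addressed whether the re-engineered interfaces disturbed other pathways. At 10 µM, 48 genes differed between the 6 pairs and the 2 wild-type libraries in limma, 20 higher and 28 lower in the pairs. This count also rested on single libraries. It was 288 without pair 14, 19 without pair 4, 9 without pair 15 and 2 without pair 8, 13 or 1, and it was 7 without wild-type replicate 1 and 2 without replicate 2. Of the 6 genes named as lowest, all but opgB belonged to the PhoP list. The lipoprotein gene borD read 17.7 ± 4.7 RPKM in the pairs (SD, n = 6) and 388 ± 165 RPKM in wild type (SD, n = 2), a log2 difference of -4.36 ± 0.31 (SE, limma adjusted p 0.000246). The outer-membrane protease gene ompT differed by -3.41, opgB by -2.59, yrbL by -2.41 and rstA and rstB by -2.39 each. The mgtA gene read higher in the pairs by 1.41 ± 0.72 (SE) and mgtL by 0.23 ± 0.38 (SE), neither called. Of the 14 PhoP targets, 6 fell over all genes tested and 7 when adjusted over the list alone. Camera called the list lower (median -0.59, and -0.38 without wild-type replicate 1). The genes that were higher were hicA at 1.56, ldhA at 1.21, slyA at 1.06, yegP at 1.04, prlF at 0.94 and osmC at 0.94. Across 16 alternative settings each, borD and ompT were called in 16, whereas rstB was called in 5 of 15 and osmC in 5 of 16.

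**Figure D3:**
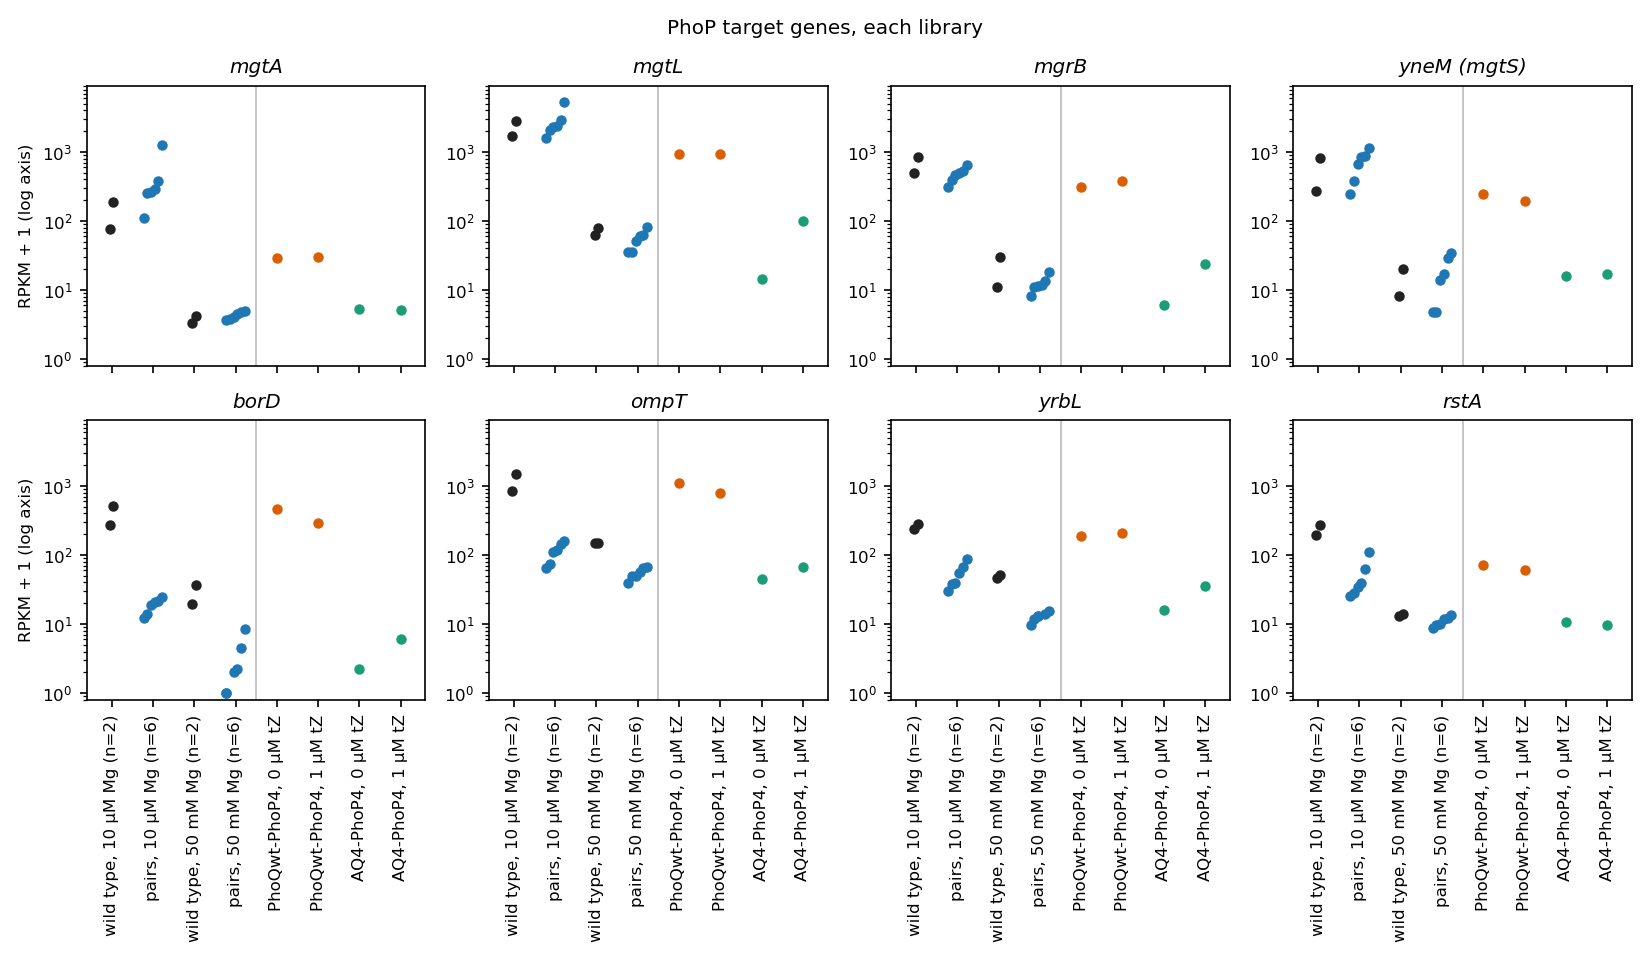
RPKM + 1 on a log axis for 8 PhoP targets, 1 point per library, by strain class and condition (wild type black, 6 pairs blue, PhoQwt-PhoP4 orange, AQ4-PhoP4 green; tZ, trans-zeatin). At 10 µM the pairs lie below wild type for borD and ompT, whereas mgtA reads 108 to 1243 RPKM in the pairs and 186 and 75.3 RPKM in wild type.

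At 50 mM, 10 genes differed, 8 higher and 2 lower in the pairs. The count was 2 without wild-type replicate 1, 31 without wild-type replicate 2, 30 without pair 4 and 6 without pair 8. The genes that were lower were yrbL at -1.95 and ompT at -1.47, so both were below wild type in both conditions. Those that were higher were led by glgS at 1.16, raiA at 0.69, cspD at 0.65, osmC at 0.58, leuL at 0.58 and erpA at 0.54. Among lists for other two-component systems, camera at 10 µM called the OmpR list (median 0.50 higher, 0 genes called), the NtrC list (median -0.44, 1 gene called, glnH at 0.59) and the ArcA-repressed list (median 0.13, 1 gene called, icd at 0.62). None of these 3 calls held without wild-type replicate 2, where the medians were 0.38, -0.14 and 0.09, and the OmpR call was also lost without pair 14 (0.54) or pair 13 (0.48). Without wild-type replicate 1 the NtrC median was -0.75 and the ArcA-repressed median 0.34, and the latter was 0.08 without pair 1 and 0.24 without pair 4. At 50 mM it called the ArcA-repressed list (median -0.19, 0 genes called). The lists for PhoB, CpxR, BaeR, RcsB, NarL/NarP, KdpE, BasR, CreB and BtsR/PyrR were not called in either condition, and their medians at 10 µM ran from -0.54 for BasR to 0.15 for PhoB. These tests average the pairs, and single libraries could stand apart. At 10 µM the BaeR median deviation was 0.85 in pair 1 (wild type 0.16 and 0.17) and the PhoB one 0.84 in pair 14 (wild type 0.07 and 0.16). Both were picked after the values were seen and have no replicates. Outside two-component systems, the RpoS list (median 0.53) and the heat-shock list (median 0.62) were higher in the pairs at 10 µM, with 2 genes called in each. The Fur list (0.74, 0 of 20 genes called) and ribosomal genes (0.14, 0 of 29 called) were also higher. The Fur median was 0.39 without pair 4, still called by camera at the preset correlation. The purine (-0.36, 2 genes called) and cold-shock (-0.93, 1 gene called) lists were lower, the cold-shock call being lost without wild-type replicate 1 (-0.88) or pair 14 (-0.82). The purine median was -0.23 without wild-type replicate 2. At 50 mM the methionine list was higher (0.38) and the histidine and tryptophan (-0.11) and ribosomal (-0.07) lists were lower, with 0 genes called in any of the 3 lists. The ribosomal median was -0.03 without wild-type replicate 1. The PhoP list was also called lower at 50 mM (median -0.17), with 2 of 14 genes lower over all genes tested, and 3 lower and 1 higher when adjusted over the list alone. That call was lost without wild-type replicate 2 (-0.11), and the median was -0.30 without wild-type replicate 1 and -0.10 without pair 13.

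Each pair was also screened alone, without replicates, for genes at least 4-fold from both wild-type libraries. At 10 µM there were 11 such genes in pair 8, 8 in pair 14, 7 in pair 15, 6 in pair 13, 11 in pair 1 and 46 in pair 4, beside 2 genes between the wild-type replicates. At 50 mM there were 2, 3, 4, 0, 1 and 31, beside 1 between the replicates. In pair 4, 40 genes were higher at 10 µM, and 15 of these belonged to the 20 Fur-repressed iron genes; at 50 mM 13 of 30 did. The enterobactin gene entC read 58.7 RPKM in pair 4 at 10 µM against 0.905 and 0.319 RPKM in wild type, fiu 73.3 against 1.71 and 1.81, and cirA 120 against 5.34 and 5.46. In the other pairs the furthest genes were mainly borD, ompT and yrbL. Exceptions were nrdI in pair 14 at 60.9 RPKM against 5.19 and 7.32, opgB in pair 8, cspA in pairs 8 and 14 at 50 mM, and fimC and fimI in pair 15 at 50 mM. Of the 130 calls over all pairs and both conditions, 128 had recovered reads. Counting intervals excluded equality with both wild-type libraries in 124 of them and lay beyond 4-fold in 74. A lower level was not shown for ibsE in pair 1, where 0 reads (against 7 and 2) allow up to 7.59 times a wild-type library, or for ydfB in pair 15, where 0 reads (against 5 and 8) allow up to 1.13 times.

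**Figure D4:**
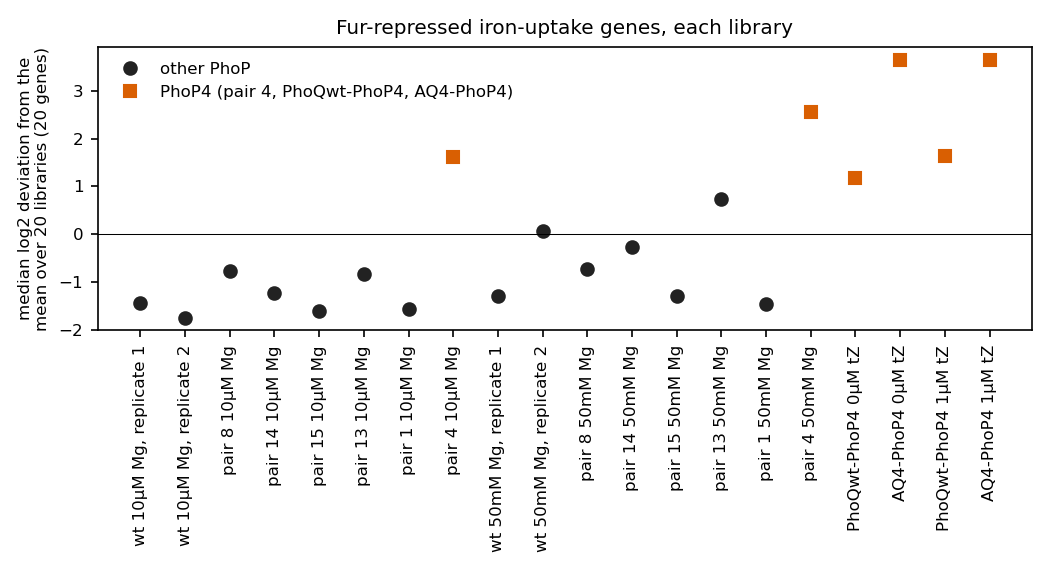
Median log2 deviation of 20 Fur-repressed iron genes from their mean over 20 libraries (y axis), 1 point per library (x axis), with strains carrying PhoP4 as squares. Libraries with PhoP4 lie at 1.17 or above and the others at 0.73 or below.

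The trans-zeatin libraries asked whether the chimera AQ4 drives PhoP4. There were no replicates, and the response of PhoQwt-PhoP4 served as background. With trans-zeatin 50 genes changed at least 2-fold in AQ4-PhoP4, 38 upward and 12 downward, and 26 changed in PhoQwt-PhoP4. The PhoP list rose by a median of 0.08 in AQ4-PhoP4, at the 95.9th percentile of 10000 random lists matched on expression, and changed by -0.16 in PhoQwt-PhoP4. In AQ4-PhoP4, 6 of the 34 lists ranked higher, led by NarL/NarP (a median of 0.94) and sulfate assimilation (0.11). For the excess over PhoQwt-PhoP4, the PhoP list ranked first of 34 by percentile, with a median of 0.39 at the 99.9th percentile. Medians were larger for the NarL/NarP (0.71), acid-resistance (0.46), BtsR/PyrR (0.44), methionine (0.40) and RpoS (0.40) lists. On the negative side, the excess of the Fur (-0.69) and cold-shock (-0.73) lists lay at percentiles 0 and 0.06. The background strain itself also moved. In PhoQwt-PhoP4 the Fur (0.49), cold-shock (0.59), NtrC (0.30), ArcA-repressed (0.25), and histidine and tryptophan (0.23) lists rose, each at about the 100th percentile. Matching used mean expression over 20 libraries, while several PhoP targets had few reads in AQ4-PhoP4. The random lists may therefore spread too little, and correlation between genes was ignored, so the percentiles rank lists and test nothing. Reads behind some targets were few, whereas others were well counted, such as slyB with 558 reads without and 1416 with trans-zeatin. Scaled to depth, the slyB ratio was 1.07 (exact 95% counting interval 0.967 to 1.18). For mgtL there were 2 reads without and 36 with trans-zeatin, a ratio of 7.57 (exact 95% counting interval 1.95 to 64.9). For mgrB the ratio was 4.63 (1.14 to 40.6), for yrbL 2.24 (1.48 to 3.52), for ompT 1.51 (1.23 to 1.87) and for mgtA 0.99 (0.643 to 1.54). Of the 14 targets, the interval lay above 1 in 5 (these 4 rising genes and pmrD), below 1 in 1 (hemL, 0.911, 0.839 to 0.991), and included 1 in 8. Without trans-zeatin, targets were already high in PhoQwt-PhoP4, with mgrB at 308 RPKM, mgtL at 945 RPKM and borD at 458 RPKM, against 4.98, 13.4 and 1.22 RPKM in AQ4-PhoP4. Genes were ranked by excess only where the log2 change in AQ4-PhoP4 was at least 2 times that in PhoQwt-PhoP4 in size. Genes that changed mainly in PhoQwt-PhoP4 were therefore not ranked, whatever their excess. Under this limit, the largest excess in AQ4-PhoP4 was in raiA (328 to 1686 RPKM), mgtL, hypA (10.2 to 41.1), yecH, nirB (16.5 to 79.6), ychH and ypfM. By size yohP, borD and ydfB also ranked among the first 10, but on 0 and 12, 1 and 10, and 2 and 18 reads in AQ4-PhoP4, and the counting interval of the excess included no excess for each. Under the same limit, the largest negative excess was in cspF (16.8 to 2.83 RPKM), then nudG, sfsB, efeU_1, efeU_2, rsxA, rnpA, yidD and yihG. For yceK, second by size, the interval again included no excess, and for efeU_1 and efeU_2 read numbers could not be recovered, so no interval was formed.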

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

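All tests of explanations in this part were chosen after the results were seen. For the first, the chi-square replaced 2 earlier counts, given beside it.

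PhoP targets in the pairs at 10 µM differed from wild type by unequal amounts. The differences of the 14 targets from wild type spread around a shared value of -0.93 with a chi-square of 22.1 per degree of freedom, and 21.3 over the 13 that rose with low magnesium in wild type, which argues against an equal log2 drop in every PhoP target and not against lower PhoP output as such; the counts looked at first were 4 of 14 above 0 and 9 more than 2 SE above the median of the 6 called targets. Nor was there less phoP transcript, since phoP read higher in the pairs by 0.38 ± 0.11 (SE), and library scaling left the median of the called targets at -2.36, beside -2.40. The PhoP4 substitutions by themselves cannot be told apart from medium for pair 4. The balance of the called targets against mgrB lay 2.15 higher in PhoQwt-PhoP4 than in pair 4. However, PhoQwt-PhoP4 was in another medium, with 2 mM MgSO4, and neither had replicates. Lower PhoP output acting on promoters of different sensitivity may remain, as may a changed preference among promoters or a background difference between the wild-type strain and the pairs, none of them tested.

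The Fur-repressed iron genes were high in every library that the labels give PhoP4 (pair 4, PhoQwt-PhoP4 and AQ4-PhoP4), from 1.17 upward, and at or below 0.73 elsewhere. Conditions of the trans-zeatin series do not account for the level in pair 4, which exceeded each other library of its magnesium condition by at least 1.83. Whether they raised the iron genes in PhoQwt-PhoP4 and AQ4-PhoP4 cannot be told, because that series held no strain without PhoP4. PhoP4 itself gave an exact two-sided permutation p of 0.0119 over 84 splits of the 9 strains, the smallest possible, with a mean difference of 3.31. The separation had been seen first, which fixed this p, and 2 of the 3 PhoP4 strains make up the whole trans-zeatin series, so the p is no evidence for PhoP4. It cannot be told apart from the iron state of single cultures, because each PhoP4 strain had 1 culture per condition and the wild-type replicates at 50 mM already differed by 1.35. Shared ancestry may also contribute in pair 4 and PhoQwt-PhoP4, which both had high flu transcript. It was not tested. AQ4-PhoP4 lacked high flu and yet had the highest mean of the iron list, 3.64 against 2.08 in pair 4 and 1.40 in PhoQwt-PhoP4. The flu transcript therefore does not track the iron genes across these strains. An effect of PhoP4 on iron genes may therefore be stated only as a hypothesis.

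In PhoQwt-PhoP4, PhoP targets were high without trans-zeatin. A library of the magnesium series in its place is argued against by phoQ, which read at most 38.5 RPKM there and at least 326 RPKM in that series. Labels of PhoQwt-PhoP4 and AQ4-PhoP4 exchanged would need a rise with trans-zeatin in the libraries labelled PhoQwt-PhoP4, where the list median changed by -0.16. That cannot decide against an exchange, because the list median rose by only 0.08 in the libraries labelled AQ4-PhoP4. Phosphorylation of PhoP4 by wild-type PhoQ may be an explanation, although phoQ transcript in that strain lay far below the magnesium series. Neither that explanation nor the reason for the low phoQ was tested.

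Chance is argued against, but not excluded, for the number of genes called between conditions in the pairs. Only 1 of 32 swaps of the conditions within pairs, the real one, gave 517 genes, and the highest other gave 11. A share of 1 in 32 is the smallest these swaps allow, so they cannot put chance below that level.

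Among the 6 pairs, 13 of 97 sets of values screened had 1 pair far from the rest, where independent, normally distributed sets would give about 4.85. Genes were screened on RPKM and not on the log2 scale, which widens high values, and the sets overlapped. The excess over 4.85 is therefore no evidence against chance, and the sets below are descriptions only. At 10 µM, pair 15 stood out in ybjX (444 RPKM, others 56.2 to 152) and rstB (42.8, others 9.04 to 18.6). Pair 8 stood out in mgtA (1243, others 108 to 384) and mgtL (5330, others 1600 to 2849). Pair 14 stood out in yjiY (1579, others 144 to 558) and livJ (34.8, others 75.8 to 92.5), and in the medians of the sulfate (0.52, others -0.98 to -0.72), histidine and tryptophan (1.13, others 0.41 to 0.64) and ribosomal (-0.25, others -0.08 to 0.02) lists. Pair 4 stood out in sufA (58.1, others 16.0 to 29.3) and the iron list (1.61, others -1.61 to -0.78), and at 50 mM in sufA (112, others 10.8 to 47.9) and nrdH (240, others 30.0 to 93.6).

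By camera at the preset correlation, 11 lists differed in magnesium response between pairs and wild type. The medians were -0.45 for PhoP targets, -0.35 for CpxR, -0.51 for methionine and -0.36 for purine genes, and 0.50 for OmpR, 0.29 for ArcA-repressed, 0.40 for RpoS, 0.47 for heat-shock, 0.18 for iron, 0.22 for ribosomal and 0.19 for histidine and tryptophan genes. The median over all genes was -0.11, and none held with an estimated correlation. At the preset correlation, the PhoP call was lost without wild-type 10 µM replicate 1 (-0.42) or pair 14 (-0.53) and the histidine and tryptophan call without 10 µM replicate 1 (0.11). The iron call was lost without pair 8 (0.08), 1 (0.16) or 4 (0.21), and its median turned negative without wild-type 10 µM replicate 2 (-0.02) or 50 mM replicate 2 (-0.46). It was 0.86 without 50 mM replicate 1, 0.36 without 10 µM replicate 1 and 0.33 without pair 13. The ArcA-repressed median was 0.48 without wild-type 10 µM replicate 1, 0.19 without 10 µM replicate 2 and 0.46 without pair 4; the histidine and tryptophan median was 0.34 without 10 µM replicate 2, 0.07 without pair 14 and 0.29 without pair 4. The methionine call was lost without 10 µM replicate 2 (-0.27). Construct sequences outside the comparisons also gave reads: ampR lay between 14.4 and 29.9 RPKM and the replication origin between 40.9 and 124 RPKM over 20 libraries. The entries PhoP (548 to 1422 RPKM), specR (3540 to 5430) and YFP (1677 to 20280) read higher. In wild type YFP read 13460 and 7814 RPKM at 10 µM and 5807 and 5474 RPKM at 50 mM. Pair 14 went the other way, at 6252 and 8124 RPKM, while each other pair read higher at 10 µM than at 50 mM. With trans-zeatin YFP went from 1677 to 2621 RPKM in AQ4-PhoP4 and from 8453 to 6270 RPKM in PhoQwt-PhoP4, without replicates.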

How the results depend on the processing

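The voom fit, the single-pair count without pair 4 and the lists without each library or pair were chosen after seeing the data. Of the 49 list calls, 33 held in every leave-out; the iron list's difference in response reversed from 0.18 to -0.02 without wild-type 10 µM replicate 2 and to -0.46 without 50 mM replicate 2, with leave-outs from -0.46 to 0.86. No named gene reversed. The balance of the wild-type response turned from 301 higher and 153 lower to 128 and 186 with median-ratio rescaling. The wild-type response called 0 genes without a filter and 17 without the variance trend, where the main count was 454, and leaving out 1 library gave 29 to 903. With replicate number as a block it called 557. For the pairs' response, leaving out 1 pair gave 284 to 649. For the difference in response, leave-outs gave 0 to 149, and the replicate block gave 0. Pairs against wild type at 10 µM gave 18 genes without a filter, 31 with median-ratio and 28 with TPM rescaling and 11 without the trend, against 48, with leave-outs at 2 to 288. At 50 mM it gave 1 without the trend and 5 with voom, against 10, with leave-outs at 2 to 31. The calls of lists, 49 in all, were 0 with an estimated correlation and 19 with fry, which tests whether genes of a list move on balance one way. The PhoP list difference of -1.22 became -1.24 with a pseudocount of 4 and -1.27 with wild-type replicates crossed, both at an exact p of 0.0357, the smallest possible, and -0.60 with list means, at 0.143. Single-pair calls, each 1 gene in 1 pair and condition, numbered 130, 449 at 2-fold and 53 without pair 4. Trans-zeatin genes in AQ4-PhoP4 numbered 50, 7 at 4-fold and 105 from 5 RPKM. Limma over all libraries, which tested the AQ4-PhoP4 change minus the PhoQwt-PhoP4 change and not the same quantity, called 0 (220 at an unadjusted p under 0.05); that fit has 1 library per trans-zeatin arm and takes its spread from wild-type replicates in other media, so its 0 says nothing about stability. The fold and RPKM limits change how many genes qualify by construction; for the other changes the cause was not tested. Over named genes and settings, calls were kept in 223 of 223 cases for the pairs' response, 192 of 222 for wild type, 109 of 190 at 10 µM and 103 of 128 at 50 mM. These genes had been named for the largest called changes, and for the magnesium responses also for all libraries moving one way. That choice favoured kept calls and an absence of reversals, so neither speaks for the stability of the other called genes.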

Other observations

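The tests and genes in this part were chosen after their values were seen. Pair 4 and PhoQwt-PhoP4 shared high transcripts that were low in the other strains; whether these depend on PhoP4 was not tested. The antigen 43 gene flu read 310 to 406 RPKM in their 4 libraries and 14.6 to 30.6 RPKM in the other 16, yeeR read 46.3 to 52.4 against 2.69 to 6.59, and yeeS 25.7 to 38.4 against 0.78 to 6.63. AQ4-PhoP4 lacked it. In pair 15, fimA read 548 to 605 RPKM against 2247 to 2848 in the other 18 libraries.

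Without pair 14, the difference in magnesium response, pairs minus wild type, was most negative in opgB (-2.66), rstB (-2.30), rstA (-2.25), ybjX (-2.16) and ompT (-1.73). It was most positive in yffS (1.37), livJ (1.32) and gltA (1.23). Because livJ and gltA fell in wild type, a positive value there means a smaller fall, or none, in the pairs.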
